A study of Homo sapiens with 2 samples.

How the data were processed

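Per the labels, NUSAP1 was precipitated from formaldehyde-fixed, sonicated chromatin of AsPC1 cells in 1 library, and input chromatin was sequenced as a further library. The authors name bcl2fastq 2.17, Trimmomatic 0.33, Bowtie 1.1.2, MACS2 2.1.0 and build hg38, without caller settings. The deposited peak list in the narrowPeak layout was the only file used. Its deposited columns hold a display score (the whole part of 10 times -log10 p in all 9043 lines), the fold enrichment as a ratio of the summit to the local background, -log10 p and -log10 q (unit neg_log10_p) from the authors' caller, and, in an other deposited column, the offset of the summit in bp. Positions are given from 1.

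The number of fragments at each summit and the caller's background expectation were worked out from the fold enrichment, read as (fragments + 1) over (background + 1), and from the Poisson -log10 p. A whole number of fragments reproducing -log10 p within 0.001 was found for all 9043 summits, with a largest error of 0.000262. When the p-values were shuffled between summits, 2.59% were matched. All of 500 simulated summits were recovered. The background had a lowest value of 0.708. At 1746 of the 9043 summits it lay within 0.002 of 1, 2 or 3 steps of 0.712 fragments (781, 905 and 60 summits). The other summits were not at these steps. A scaled control library would give such steps. That this control was the input library is inferred from the steps and is not stated by the authors; no file of the input library was used here, so the background values are not direct measurements of it. If the caller's default genome size of 2.7e+09 was used, that lowest value corresponds to about 9.61e+06 immunoprecipitate reads. Peak widths had a median of 199 bp and 51.0% were at that smallest width.

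Genes came from a RefSeq table for the same build with the start and end of each gene but no strand, exons or sequence. Of its 59792 genes, 831 on other sequences were left out. The planned distance to a transcription start was replaced by the distance to the nearer end of a protein-coding or long non-coding RNA gene, within 1 kb. Location classes were gene end, inside a gene and outside genes. Summits were compared with 1000 random placements on the same chromosome outside stretches of over 1 Mb without genes and peaks, and with 1000 placements that shift each summit by 100 kb to 1 Mb; the latter were added after the data were seen. Ranges hold 95% of placements. With 200 of the summits moved to gene ends in a simulation, an excess of 182 was recovered, and -4.64 with none moved.

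For each list, members with a summit at a gene end were counted and placed among 10000 random lists of the same size, drawn from protein-coding genes, or from non-coding genes for the non-coding list, matched in 10 strata on summits within 2.5 Mb. Counts in gene bodies were matched on gene length and summit density, in 5 strata each. The list of oxidative phosphorylation lost NDUFA4, absent from the table. A planted list of 30 genes with 8 hits reached percentile 100. Genes are named by a rule: NUSAP1, LDHA and glycolysis genes with a summit at an end; genes of the 20 summits with the smallest q; the 20 protein-coding genes with the highest fold enrichment at an end; and up to 4 members per list. The genes of small RNAs and of gene bodies in the closing observations, SLC16A7, PFKFB2, PFKM, PFKFB3, MKRN2, B4GALT7, MRPL21, IGHMBP2 and MALAT1 were named outside it, after their values were seen, as were the windows on chromosomes 3, 8 and 18. Also outside the rule were RNA45SN4 and RNA18SP4, and HK1, HK2, GAPDH, PGK1, ENO1 and PKM as examples of the glycolysis list.

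The lists, main comparisons and main alternatives were chosen before the data were examined. Matching on summit density, in place of the planned CpG content, was not part of that plan. Neither were the counts in gene bodies and the correlations across chromosomes. Summits per Mb used the span of genes and peaks. Correlations across chromosomes used 100000 permutations and Benjamini-Hochberg adjustment. Alternatives were stricter q and fold limits, windows of 500 bp and 5 kb, any overlap in place of the summit, peaks within 1 kb merged, and lists without matching. Limits at q 0.05, at 7 fragments and at a background of 3 times the lowest, and lists matched on transcript number, were added after the data were seen. Motif counts, matching on GC or CpG content and a single start per gene need sequence or strand and were not run. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.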

Results

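Chromatin immunoprecipitation with sequencing (ChIP-seq) was made in AsPC1 cells, an established cell line from a human pancreatic ductal adenocarcinoma. NUSAP1, a nucleolar and spindle-associated protein, was precipitated in 1 library, and 1 further library was made from input chromatin. There were no replicates, so the peak caller's q was the only test of single summits, and the percentiles and ranges given here describe this single peak list. The values are those of the peak list of the NUSAP1 library, which held 9043 summits in 9033 regions on genome build hg38. The total number of reads per library was not part of the list.

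The LDHA gene encodes the lactate dehydrogenase subunit that turns pyruvate into lactate, and the series title links it to NUSAP1 and glycolysis. No NUSAP1 summit lay in LDHA (gene ID 3939, chromosome 11, 18394563 to 18408425) or within 1 kb of its ends. The single summit within 50 kb was at position 18378961, 15.6 kb below the lower end of the gene. It had a fold enrichment of 2.57, a p of 0.00294 and a q of 1 from the caller, and rested on 4 fragments. The nearest summit on the other side lay 92.5 kb beyond the upper end, with a fold enrichment of 3.12 and a q of 0.779. In this list, 13.6% of the 19866 protein-coding genes had a summit in the body or within 1 kb. An absence at LDHA alone therefore says little. NUSAP1 itself (gene ID 51203, chromosome 15, 41332881 to 41381046) had no summit within 50 kb, and its nearest summits were 409 kb below and 573 kb above it.

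None of the 28 glycolysis genes, from the hexokinases HK1 and HK2 to GAPDH, PGK1, ENO1 and PKM, had a summit within 1 kb of either end of the gene. Random lists of the same size and similar local summit density held a mean of 0.618 such genes, with 95% of lists between 0 and 2, so a depletion was not detectable with a list this sparse. PFKFB3, which makes the activator of phosphofructokinase fructose 2,6-bisphosphate, held a summit in its body with a fold enrichment of 2.92 and a q of 1. Summits lay 2220 bp beyond the upper end of PFKFB2 (fold enrichment 4.20, q 0.258) and 2101 bp beyond that of PFKM (3.32, q 0.779). Among 27 genes of lactate, glucose and pyruvate handling, none had a summit at a gene end, and the monocarboxylate transporter gene SLC16A7 held a summit in its body (q 1).

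NUSAP1 summits with q under 0.05 lay within 1 kb of an end of 16 of the 19866 protein-coding genes. The largest fold enrichment of the whole list, 11.4, was at UNC5B, a netrin receptor gene (gene ID 219699). That peak spanned 71212234 to 71212631 on chromosome 10, its summit was 123 bp below the lower end of the gene, and it rested on 24 fragments over an expected 1.19 (q 2.23e-18). TTC21B, whose product works in intraflagellar transport, followed with a fold enrichment of 6.15 (chromosome 2, 165953766 to 165954048, q 2.93e-05). The mitochondrial ribosomal protein gene MRPL16 had 5.56 (chromosome 11, 59810702 to 59810956, q 0.00158), and the lamin B1 gene LMNB1 had 5.16 (chromosome 5, 126776694 to 126777015, q 0.00604).

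Several of these peaks lay within 1 kb of an end of neighbouring or overlapping genes and were counted for both. The POLDIP2 and VMA12 genes shared a summit (fold enrichment 5.12, q 0.00672), as did SHARPIN, of the linear ubiquitin ligase complex, and MAF1, which encodes a repressor of RNA polymerase III (4.87, q 0.0368). MRPL21 and the helicase gene IGHMBP2 shared a summit with a fold enrichment of 3.90 (q 0.0406), and FAM43A shared its own with LOC124909474 (4.49, q 0.0158). The remaining genes with q under 0.05 were IFI44, an interferon-induced gene, SRPRB, MKRN2 and B4GALT7, with fold enrichments between 3.95 and 5.18. Among the genes with q under 0.05, B4GALT7, MRPL21 with IGHMBP2, and MKRN2 stood on a background of at least 3 times the lowest (3.56, 2.85 and 2.12 fragments). MKRN2 was barely above that limit of 2.12. The 20 protein-coding genes with the highest fold enrichment at an end also included SNAPC3, a subunit of the complex that activates small nuclear RNA genes, ACSF3, HTR7, the mismatch repair gene PMS1 with ORMDL1, and RFXANK with BORCS8 and its BORCS8-MEF2B readthrough. These had fold enrichments from 4.52 to 4.68 and q near 0.0857, and so did not pass 0.05.

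Over the 9002 summits on the chromosomes, 624 (6.93%, 95% Wilson interval 6.43 to 7.48) were within 1 kb of an end of a protein-coding or long non-coding RNA gene. Random positions on the same chromosomes gave a mean of 432, with 95% of 1000 placements between 393 and 469, a ratio of 1.45. The ratio was higher for summits with 7 or more fragments than for those with fewer. Among the 29 summits with -log10 q of at least 5 it was 0.589, with 1 protein-coding gene (UNC5B) counted, too few to show a reversal. With 4 or 5 fragments at the summit the share was 5.81% (ratio 1.24 to positions shifted by 100 kb to 1 Mb), with 6 fragments it was 7.10% (1.49), and with 7 or more it was 12.9%, 138 of 1070 (2.69). Within 250 bp of a gene end, summits of 7 or more fragments were 4.95 times as frequent as at shifted positions, and from 1 kb outward none of the distance classes held an excess. Summits inside genes and over 1 kb from an end numbered 4593 (51.0%), 0.931 times the random mean, and those outside genes 3785 (42.0%), 1.04 times the random mean. At 7 or more fragments the shares were 43.0% inside (0.787) and 44.1% outside (1.09). At q under 0.05 they were 18.6% (0.340) and 65.5% (1.63), with ratios of 0.501 and 1.11 to shifted positions. The gene table gives neither strand nor transcription start, so a gene end here is either end of the annotated gene.

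**Figure D1:**
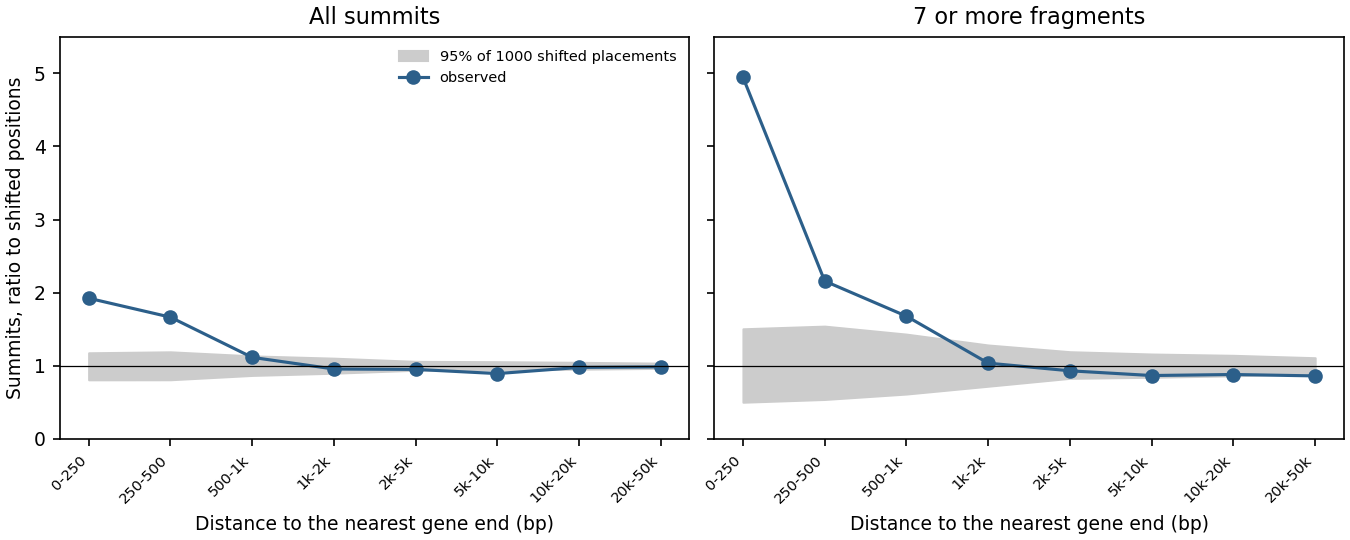
Ratio of the number of summits to the mean of 1000 placements shifted by 100 kb to 1 Mb (vertical axis) in classes of distance to the nearest end of a protein-coding or long non-coding RNA gene (horizontal axis, bp), for all summits and for those with 7 or more fragments. Points are the observed ratios and the grey band holds 95% of the placements; within 250 bp the ratio is 1.92 for all summits and 4.95 for those with 7 or more fragments.

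Of 16 gene lists fixed before the data were examined, the highly transcribed non-coding RNA genes stood highest. Summits lay within 1 kb of an end of 5 of the 34: the spliceosomal U1 genes RNU1-1 and RNU1-2, the U5 gene RNU5A-1, the U12 gene RNU12, and MALAT1. Random lists of non-coding genes, most of them long non-coding RNA genes and pseudogenes, held a mean of 0.436 such genes (95% between 0 and 2; percentile 99.98). Without summits on a background of at least 3 times the lowest, 3 were left (percentile 99.4). RNU1-2 had a fold enrichment of 4.72 with a q of 0.0368, the sole member of any of the 16 lists with q under 0.05. RNU5A-1 had 4.14 (q 0.162), RNU1-1 had 3.81 (q 0.113), RNU12 had 3.06 (q 0.820) and MALAT1 had 2.34 (q 1). The abundant housekeeping genes followed, with summits at 3 of 29 (EEF1A1, TUBA1A and TUBB, percentile 98.1). This lay within the random range, as 95% of random lists held between 0 and 3. None had q below 0.779. With 7 or more fragments required, EEF1A1 was left (percentile 90.5). Without summits on a background of at least 3 times the lowest, 2 were left (percentile 91.9). EEF1A1 was lost there, at 2.14 fragments, just above the limit of 2.12.

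The other lists lay between percentiles 18.6 and 83.2. With a window of 5 kb in place of 1 kb, HIF targets rose to 5 of 27 (percentile 97.9) and abundant housekeeping genes fell to percentile 77.6. Ribosomal protein genes had summits at 3 of 77 (RPL4, RPL35 and RPL6), replication-dependent histone genes at 2 of 53 (H4C3 and H3C6). The HIF targets had 1 of 27 (VEGFA, the vascular endothelial growth factor), the MYC targets 1 of 30 (NME1), oxidative phosphorylation 1 of 41 (NDUFB10), and mitosis and spindle genes 1 of 36 (the kinetochore gene NUF2). Ductal and epithelial identity genes had 1 of 26 (FOXA2), immediate early and stress genes 1 of 33 (FOSL1) and p53 targets 1 of 20 (PLK2). EMT and invasion genes (30), acinar and islet genes (26) and genes of other lineages such as photoreceptor, muscle and blood genes (34) had none. The smallest q among these members was 0.418, at PLK2. NME1, FOSL1 and PLK2 were not counted once summits on a background of at least 3 times the lowest were left out. Each stood at 2.14 fragments, just above the limit of 2.12.

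**Figure D2:**
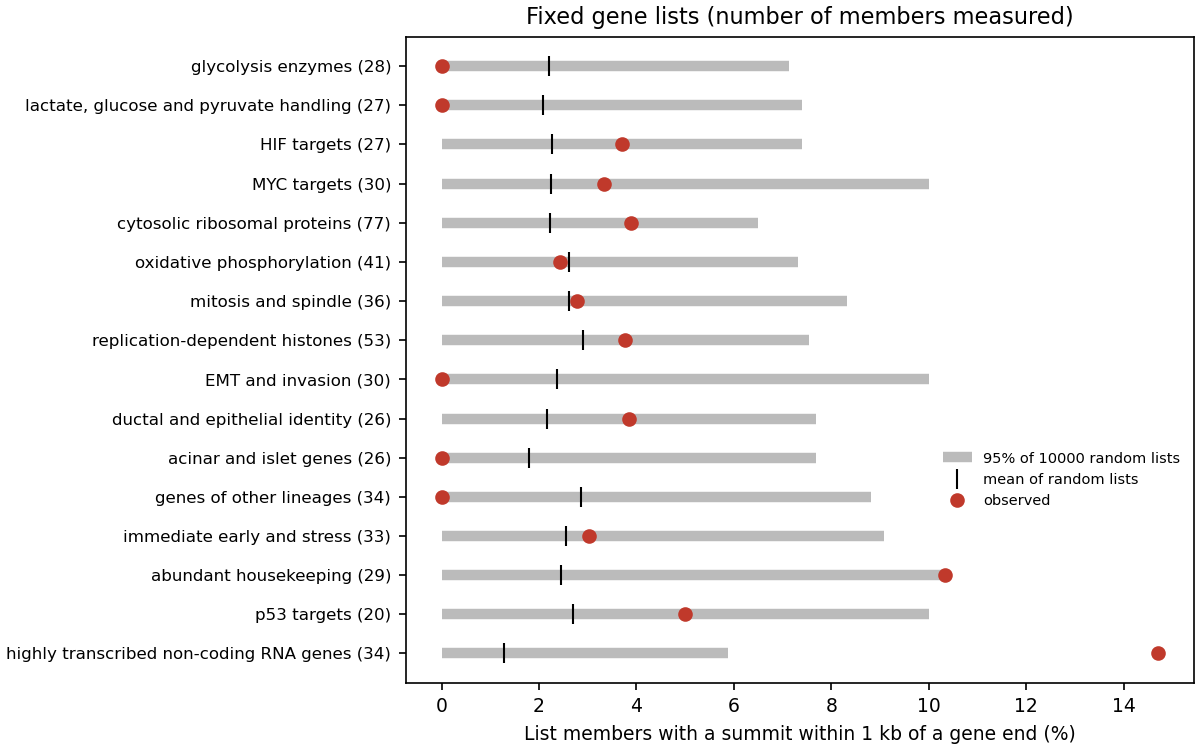
Percentage of the members of each of 16 fixed gene lists with a summit within 1 kb of a gene end (horizontal axis), with the number of members measured in brackets. Red points are observed, ticks are the means and grey bars hold 95% of 10000 random lists of the same size matched on local summit density; highly transcribed non-coding RNA genes stand at 14.7%, glycolysis enzymes at 0%.

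The strongest summits by the caller's q lay mostly in sequence without annotated protein-coding genes. On chromosome 16, 7 summits between 34576395 and 34593608 and 8 between 46380811 and 46399612, on either side of the centromere, had q under 0.05 with fold enrichments of 1.69 to 2.44 and 1.37 to 2.28. On chromosome 17, 7 lay between 23016239 and 26619801, and on chromosome 1, 3 lay between 143213139 and 143264767. Of the 20 summits with the smallest q, UNC5B was the single gene with an end within 5 kb, or a body over the summit, among those on chromosomes; 7 others were on sequences not placed on a chromosome.

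The list as a whole was weakly supported. At the summit, the number of immunoprecipitated fragments had a median of 5, and 7941 summits (87.8%) had 4 to 6. The median fold enrichment was 3.01 (quartiles 2.74 and 3.51). No listed summit had a p above 0.005 from the caller, and 134 summits (1.48%, 95% Wilson interval 1.25 to 1.75) had q under 0.05, while 7512 (83.1%) had q of 0.5 or more. None of the summits with fewer than 8 fragments had q under 0.05. Of the 134, 63 stood on a background expectation of at least 3 times the lowest in the list, with a median fold enrichment of 2.44, and 71 stood on a lower background, with a median of 5.26.

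**Figure D3:**
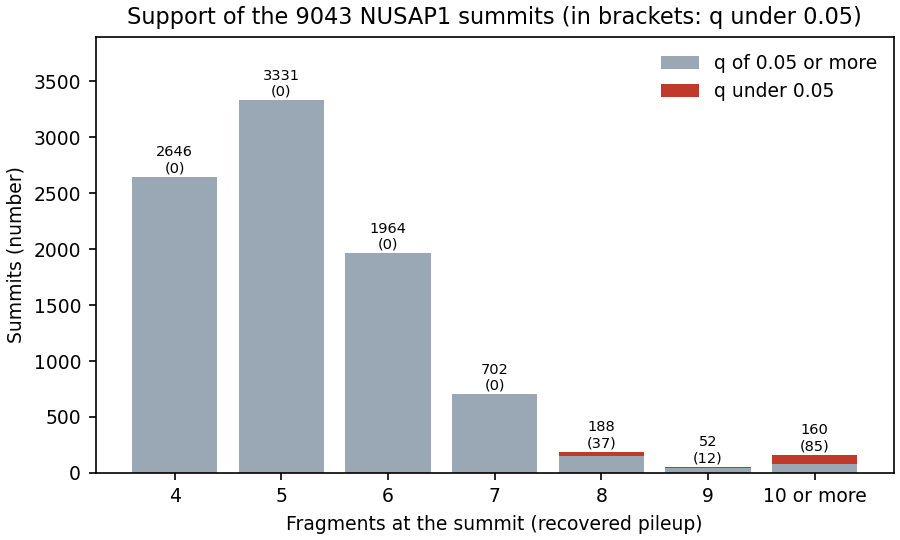
Number of NUSAP1 summits (vertical axis) by the number of fragments at the summit (horizontal axis), with the number of q under 0.05 in brackets and in red. Summits of 4, 5 and 6 fragments number 2646, 3331 and 1964, and none of them has q under 0.05.

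Summits were unevenly spread over the chromosomes. Chromosome 11 had 6.18 summits per Mb of sequence spanned by genes and peaks (95% Poisson interval 5.76 to 6.62, counting error only), chromosome 6 had 5.29 and chromosome 3 had 5.03. Chromosome 4 had 0.728 (0.611 to 0.862), a ratio of 8.48 between chromosomes 11 and 4 that was 13.6 at 7 or more fragments. At q under 0.05 the ratio was 4.97, from 7 summits on chromosome 11 and 2 on chromosome 4. At a fold enrichment of at least 5, which 54 summits of the whole list reached, it was 4.26. These last 2 values rest on too few summits to show a dependence on the limit. Chromosomes 13 and 14 had 0.842 and 0.847. Chromosome X had the lowest value of the 23 chromosomes compared, 0.569 (0.455 to 0.703). Within chromosomes the number changed in steps. On chromosome 3 it went from 4 summits between 120 and 130 Mb to 113 between 130 and 140 Mb, on chromosome 8 from 68 between 120 and 130 Mb to 5 in the next 10 Mb, and on chromosome 18 from 9 between 60 and 70 Mb to 70 between 70 and 80 Mb.

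Across 23 chromosomes of this single library, summits per Mb fell with the percentage of summits at the lowest background expectation (Pearson r -0.77, Spearman rho -0.75; two-sided permutation p 2e-05 and 6e-05, adjusted over 3 relations 6e-05 and 0.00018; 2e-05 is the smallest the permutations can give). Without the 2 chromosomes farthest from the median, r was -0.77. Summits per Mb rose with the median background (r 0.63, rho 0.57; permutation p 0.00096 and 0.0053, adjusted 0.0014 and 0.0079; r 0.59 without 2 chromosomes). With protein-coding genes per Mb, r was 0.017 and rho 0.15 (permutation p 0.92 and 0.49, which the adjustment left unchanged). Without 2 chromosomes this r was -0.0018. The permutations treat chromosomes as exchangeable, and in the 2 relations with the background both measures came from the same summits. The p-values describe the chromosomes of this list and no spread between samples. These correlations were not part of the original plan.

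**Figure D4:**
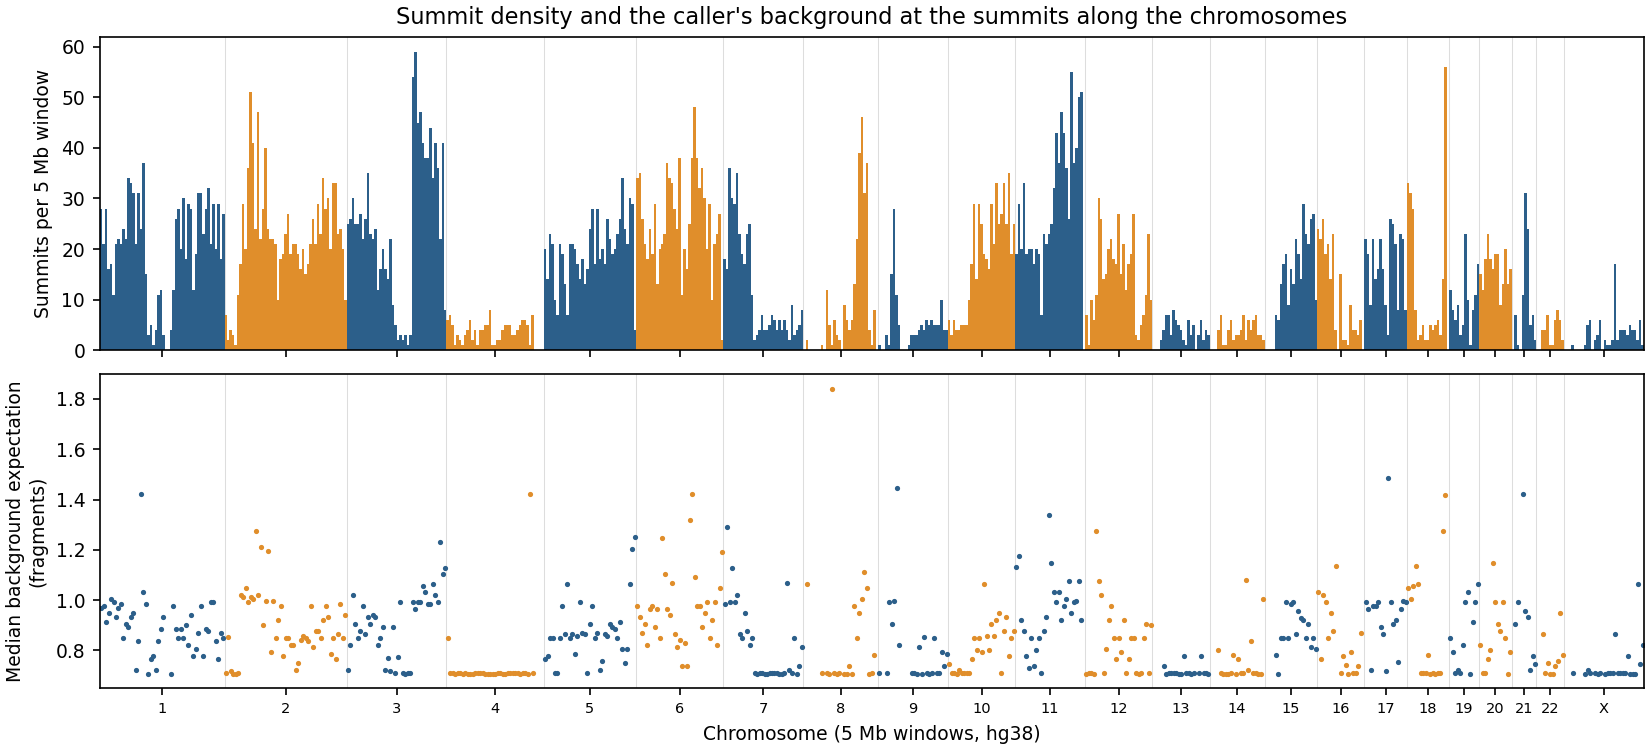
Number of NUSAP1 summits in 5 Mb windows (upper panel) and the median background expectation at those summits in fragments (lower panel) along the chromosomes, in alternating colours. The change on chromosome 3 at 130 Mb, from 4 to 113 summits per 10 Mb, appears in both panels.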

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

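The tests on the strongest summits and on chance calls were chosen only after the result was seen; those on segments and on the background at gene ends were set before. The background is the caller's expectation at the summit, and its origin in the input library is inferred, not stated.

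Sequences not placed on a chromosome, outside the gene comparisons, held 21 summits with q under 0.05. Of these, 11 were on an unlocalized sequence of chromosome 22, with fold enrichments from 3.25 to 10.4, and 5 were on a further unplaced sequence, with fold enrichments from 1.38 to 2.64 on a median background of 204 fragments. The smallest q of the whole list was at position 135756 of the chromosome 22 sequence, with 147 fragments over an expected 23.5 (fold enrichment 6.04). The gene table places the ribosomal RNA gene RNA45SN4 at 122273 to 135645 of a chromosome 22 sequence it does not name. If that is the same sequence, which was not tested, the summit at 135756 lies 111 bp beyond the gene, and the summits with the highest folds, at 170032 and 173213, lie 34387 and 37568 bp beyond it, on either side of the 18S ribosomal RNA pseudogene RNA18SP4 (171012 to 172880).

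The strongest summits may reflect multi-copy sequence. Such sequence would gather reads in the precipitate and, if the background was taken from the input library, there too. Of the 20 with the smallest q, 19 stood on a background of at least 3 times the lowest, UNC5B being the exception. The ranking by q largely sets this count, so it cannot decide the question. On its low background UNC5B entered with the highest fold of the list, 11.4, while summits on a high background entered from 1.85. Whether the summits of 10.3 and 10.4 fold on the chromosome 22 sequence, at 170032 and 173213, hold NUSAP1 stays open. No biological explanation was tested.

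The segments rich in summits may differ from the poor ones in DNA content. At a fixed 5 fragments per summit, the median background was 0.977 (quartiles 0.850 and 1.13) in the 140 densest 5 Mb windows and 0.712 (0.708 and 0.765) in the 141 sparsest, a difference of 0.266. Gene density is argued against as the main source, with a rho of 0.11 between genes and summits across the windows. Within the 23 chromosomes this rho had a median of 0.055 and ran from -0.26 to 0.63, so a contribution of gene density stays open. Reading the background as a measure of DNA content requires that it came from the input library, and even then only above its lowest level. At 5 fragments, 71.2% of summits in the sparsest windows stood at the lowest background, against 9.65% in the densest. The sparse median of 0.712 is therefore set by that level. The limit on p in the list also bounds the background at 5 fragments from above. The difference of 0.266 thus gives a direction but no size for a difference in DNA content. An effect of chromatin state stays open and was not tested.

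Evenly spread chance calls on few fragments would not give the excess at gene ends. The ratio to shifted positions rose from 1.24 at 4 or 5 fragments to 2.69 at 7 or more (2.12 to 3.54 over 95% of placements). The rise cannot exclude chance calls where the background is raised at gene ends, since such calls could also rise with fragments. A background raised at gene ends could contribute: at 5 fragments it was higher there by 0.0850, at 4, 6 and 7 fragments by 0.0425, 0.0283 and 0.290. Among summits of 7 or more fragments with a background under 3 times the lowest, the ratio was 2.52. Binding of NUSAP1 and a general recovery of open chromatin in the precipitate stay open, and no biological explanation was tested.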

How the results depend on the processing

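Limits of q under 0.05, of 7 or more fragments and of low background, shifted positions and matching on transcript number were chosen only after the data were seen. Stricter limits keep fewer summits by construction. The list fell to 44 summits at -log10 q of at least 5, 54 at fold enrichment of at least 5, 4521 in the upper part by q, 134 at q under 0.05 and 1102 at 7 or more fragments. In the same order, protein-coding genes with a summit at an end fell to 1, 7, 236, 16 and 124, and the LDHA region went from 1 summit to 0 under each of the 5. The percentage at gene ends was 3.45 (29 summits on chromosomes), 21.3 (47), 15.9 (113) and 12.9 (1070) at -log10 q of 5, fold of 5, q of 0.05 and 7 fragments. The ratio to random positions was 0.589 at -log10 q of 5, with 1 protein-coding gene counted, too few to show a reversal. There, 25 of the 29 summits stand on a background of at least 3 times the lowest. The ratio was over 1 at every other setting run. Windows of 500 bp and 5 kb gave 4.42% and 20.3%, 293 and 1270 genes, and any overlap gave 7.48%; at 5 kb, 2 glycolysis genes (PFKFB2, PFKM) were counted, HIF targets went from 1 to 5 of 27 (percentile 70.6 to 97.9) and abundant housekeeping genes fell from percentile 98.1 to 77.6 with 3 genes, so the order of the lists depends on the window. The ratio of chromosome 11 to 4 was 13.6 at 7 fragments, 4.97 at q of 0.05 (7 summits against 2) and 4.26 at fold of 5. The last 2 values rest on too few summits to show a dependence on the limit, and the cause was not tested. At -log10 q of 5 chromosome 4 had no summit, so no ratio. Merging peaks within 1 kb, leaving out unplaced sequences, low background alone and shifted positions kept each main result run under them; low background left 3 of the 5 non-coding RNA genes and 2 of the 3 housekeeping genes (percentile 91.9) and took MYC targets, immediate early and stress genes and p53 targets from 1 to 0, and merging took immediate early and stress genes from 1 to 0. Under low background, the lost members NME1, FOSL1, PLK2 and EEF1A1 each stood at 2.14 fragments, just above the limit of 2.12. All 16 lists stayed on the same side of their random range without matching and with matching on transcript number. Matching on GC or CpG, a single start per gene and motifs were not run. Most summits rest on 4 to 6 fragments, which limits what the list counts can show; whether sequencing depth or weak enrichment lies behind it was not tested.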

Other observations

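The count of facing gene ends and the small RNA genes below were chosen only after the data were seen. Small nuclear RNA genes of any kind had 10 summits within 1 kb of an end, against a mean of 0.822 at shifted positions (95% between 0 and 3), and 6 against 0.11 with 7 or more fragments. Beside the U1, U5 and U12 genes of the fixed list, they included the U1 variants RNVU1-14 (fold enrichment 4.02, q 0.418) and RNVU1-31 (2.89, q 0.944) on chromosome 1, RNU5E-1 (2.64, q 1), and LOC124904138 on chromosome 17 (3.68, q 0.00315, with 21 fragments over an expected 4.98). Small nucleolar RNA genes as a class had 5 summits against 7.10 at shifted positions (percentile 23.5), and 4 against 0.839 with 7 or more fragments. The U3 gene SNORD3A, which acts in ribosomal RNA processing, had a summit with a fold enrichment of 7.43 (q 1.03e-08, chromosome 17, 19188022 to 19188281). Its neighbours SNORD3B-2 and SNORD3D had 3.07 (q 0.418) and 2.47 (q 0.825). Transfer RNA genes had 9 summits against 2.73 (95% between 0 and 7), none with q below 0.779. With 7 or more fragments they had 1 against 0.269 (95% between 0 and 2, percentile 86.65). Pseudogenes had 129 against 126. Some of these small RNA genes have near-identical copies, and how reads with several matching places were treated is not stated.

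Summits within 1 kb of both the upper end of a protein-coding gene and the lower end of a neighbouring gene, as at POLDIP2 and VMA12, SHARPIN and MAF1 or ORMDL1 and PMS1, numbered 54, against 20.4 at shifted positions (95% between 12 and 29). With 7 or more fragments there were 22 against 2.56, a ratio of 8.61, while summits near an end of a single kind numbered 81 against 25.3, a ratio of 3.20. Whether these neighbours point away from each other cannot be read from a table without strand.

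Across protein-coding genes, 2702 of 19866 (13.6%) had a summit in the body or within 1 kb, and 441 (2.22%) at an end. Counted in the body or within 1 kb, MYC targets had 5 of 30 (PPAT, PAICS, NPM1, WDR43 and NME1) against a mean of 2.32 in random lists (percentile 95.6), with PPAT and PAICS sharing a summit, and glycolysis genes 1 of 28 against 2.99 (percentile 10.2).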
